A study of Homo sapiens with 80 samples.

How the data were processed

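The series held 80 samples. Gene counts for 42 libraries, in 5 deposited tables, were analysed. The other 38 samples were ChIP-seq libraries, for which no table of values was available, and they were not analysed here. The libraries came from SU-DHL-1 and KI-JK, established lines of ALK-positive anaplastic large cell lymphoma, a T-cell lymphoma. Per the labels, the regrown cells were 3 independent pools of SU-DHL-1 that had become resistant under rising lenalidomide and were then kept free of drug for at least 2 months. PRO-seq (precision run-on sequencing, which reads RNA still being made by engaged polymerase) covered 6 SU-DHL-1 libraries, DGE (sequencing of transcript ends for digital gene expression) 12, and RNA-seq 24, of which 6 were from KI-JK. Every group had 3 libraries.

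The values in the deposited tables were counts per gene, as whole numbers with a different total for each library, and the authors had applied no normalization to them. Per the submitters' processing notes, PRO-seq reads were trimmed with cutadapt 1.14, aligned to hg38 with Bowtie 1.2.2 and counted with featureCounts 1.6.2. The same notes list FastQC, Bowtie2 2.2.3, DESeq2 and hg19 for DGE, and STAR 2.6.1d, DESeq2 1.20.0, edgeR 3.24.3 and hg38 for RNA-seq. For RNA-seq the counting tool and its treatment of overlapping genes were not stated, and for DGE it was not stated whether molecular identifiers had been collapsed. Intervals and floors given for folds therefore cover counting error only. The deposited tables held counts for 17792 genes in PRO-seq, 17463 in DGE and 58735 in RNA-seq. Totals per library ran from 33.5 M to 47.2 M in PRO-seq, from 41571 to 395827 in DGE and from 14.4 M to 28.9 M in RNA-seq. In the RNA-seq data 27 gene names had been turned into dates by a spreadsheet, and these took the symbol that the reference pairs with their gene identifier. The 17 such names in DGE, which has no identifiers, were left as they were. No pair of replicates within a group was a duplicate (smallest chi-square per degree of freedom 1.36).

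Each comparison was a negative binomial quasi-likelihood test in edgeR 4.0.16 (filterByExpr, TMM scaling, glmQLFit with its defaults, R 4.3.3), fitted to only the groups compared, with Benjamini-Hochberg adjustment over all genes tested. A gene was called when its adjusted p was under 0.05. All tests were two-sided, each value printed as log2 fold change ± SE rests on 3 libraries per group, and the SE was taken from the test statistic (the fitted log2 change divided by the square root of F). Levels are means of CPM, counts scaled to 1 common library total. There were 12 comparisons, of which 9 set 1 group of 3 against another and 3 were interactions, that is, differences between 2 responses. A fold against a group with no counts was computed against a floor of 3 counts over the group and is given as "at least", and with 1 to 3 counts a ratio is given with its 95% exact counting interval. Fitted log2 values of such genes depend on the prior count of the fit and are no bounds.

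The comparisons, the tests, 25 gene lists and the rule for naming genes were fixed before the data were examined. Named were the design genes (ZFP91, IKZF1, IKZF3, CRBN, CSNK2B, CSNK2A1, JUN, BATF3, IRF4 and MYC), up to 10 called genes per direction with the largest fold change, and up to 4 called members of each list by p, or 2 values where no member was called. The largest changes were taken among genes with an average log2 CPM of at least 1 and no overlap between the groups' CPM values (10% of arrangements of 3 against 3 show none by chance, and interactions had no such condition), leaving out symbols that only name a locus or clone. Not every gene that the rule names is printed. The result of 1 gene is not reported here. The lists covered the interferon response, MHC class I presentation, MHC class II presentation, IMiD neosubstrates (proteins that lenalidomide and related drugs bring to cereblon), the CRL4 cereblon machinery, casein kinase 2, AP-1 and BATF factors, the ALK STAT3 program, T cell receptor and identity genes, cytokines and chemokines, NF-kB targets, the cell cycle, p53 targets, MYC and ribosome biogenesis, cholesterol and fatty acid synthesis, the amino acid response and UPR, hypoxia and glycolysis, apoptosis regulators, drug efflux, heat shock and stress, mitochondrially encoded genes, replication-dependent histones, and markers of B cells, myeloid cells and epithelial or stromal cells. Each list was tested against the other genes with camera from limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison, and again with an estimated correlation. Members were counted as called over all genes and, for called lists given with counts, also adjusted over the list alone where that differed. For lists that were not called such counts are mostly left out.

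Overlaps between comparisons were counted per direction among genes tested in both and tested with Fisher's exact test, two-sided. They are given beside the number that independence gives, and correlations of log2 changes are across genes, which are not independent replicates. Genes with at least a 2-fold change in PRO-seq formed an up set and a down set, which camera tested in 5 comparisons that share no library with PRO-seq. Running medians along chromosomes used 25 genes with an average log2 CPM over 2, and a stretch was called where the median lay beyond the largest of 100 shuffles of gene positions, with stretches less than 5 genes apart joined. Neighbours of a gene were its 24 nearest genes. Figures were drawn with matplotlib 3.10.9.

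Alternatives were DESeq2 1.42.0, edgeR with DESeq2's size factors or with library size only, a filter of at least 1 CPM in 3 libraries, no filter on low counts, all 4 groups of a table in 1 fit, each library left out in turn, a replicate block, a minimum absolute log2 fold change of 1 for overlaps, a rotation test (fry) for lists, and, chosen after the data were seen, thinning to the smallest library (for KI-JK, of SU-DHL-1), leaving out genes in chromosome stretches, a library score as a covariate, and lists with each library left out. Labels show that regrown pools 1 to 3 are shared by the arms of the drug and knockout comparisons in regrown cells, so the block is a paired test there. Nothing in the labels says whether the parental replicates, or those of the vector comparisons, were separate cultures. Their p-values measure the spread between samples. The pairing was checked on the counts, and in no comparison did every pair of libraries with the same number correlate above 0.1 beyond its group.

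The procedure was tested on simulated data with 200 genes changed 2-fold at the depth and spread of each comparison. It recovered 78% of these genes in the PRO-seq comparison with 7 false calls, 36% and 17.5% for lenalidomide in parental and regrown cells, 44% for regrown against parental cells in DGE, and 8% for the DGE interaction. Recovery was 76% and 74.5% for ZFP91 knockout in parental and regrown cells, 73.5% for regrown against parental cells in RNA-seq, and 59% for the knockout interaction. For CSNK2B it was 86% in SU-DHL-1, 79% in KI-JK and 71% for the difference between the lines. No simulated gene was called in the wrong direction. False calls numbered 16 beside 149 recovered genes for the knockout in regrown cells and 14 beside 172 for CSNK2B in SU-DHL-1. They numbered 13 beside 142 for the difference between the lines and 3 beside 16 for the DGE interaction. In the other comparisons they ran from 1 to 11. Genes were simulated independently, so the test holds no difference between libraries that many genes share.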

Results

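Gene activity was counted in 42 libraries in 14 groups of 3. PRO-seq compared parental SU-DHL-1 cells with the 3 regrown pools, at 33.5 to 47.2 M counts per library. DGE compared 18 h of 2.5 µM lenalidomide with the solvent DMSO in parental and in regrown cells. Its libraries held 41571 to 395827 counts, with the lowest total in parental lenalidomide replicate 3. RNA-seq compared cells in which doxycycline (1 µg/ml, 96 h) had induced a ZFP91 guide RNA and Cas9 cutting with cells given no doxycycline, in both backgrounds, at 15.4 to 23.1 M counts. RNA-seq also compared a CSNK2B vector with an empty vector in SU-DHL-1 (14.4 to 24.1 M counts) and in KI-JK (23.1 to 28.9 M counts). Lenalidomide makes the ubiquitin ligase adaptor cereblon, the product of CRBN, bind and degrade zinc finger proteins such as IKZF1, IKZF3 and ZFP91.

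How did transcription differ in cells that had become resistant to lenalidomide? In PRO-seq, CSNK2B, which encodes the regulatory subunit of casein kinase 2, rose by 2.05 ± 0.14 on the log2 scale in regrown cells (adjusted p = 6.26e-06), from between 6.75 and 8.36 to between 30.7 and 34.4 CPM. CSNK2A1, which encodes a catalytic subunit of the same kinase, fell by 0.98 ± 0.11, and IRF4, a lymphoid transcription factor, fell by 1.23 ± 0.24. PTPRC, the gene of the leukocyte phosphatase CD45, rose from 2.04 to 117 CPM (5.84 ± 0.33). The cereblon gene and these drug targets had no call here. CRBN gave 0.28 ± 0.10 (adjusted p = 0.0561, and 0.0409 with library size only), IKZF1 0.15 ± 0.14 and ZFP91 -0.25 ± 0.12 (adjusted p = 0.139).

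Among the largest rises in PRO-seq were S100A9, a calcium-binding alarmin of myeloid cells (7.76 ± 0.83), SPAG16, a sperm axoneme gene (5.87 ± 0.49), and PIK3CG, a catalytic PI3-kinase subunit (5.04 ± 0.27). The zinc finger gene ZNF551 had 3 counts over the parental libraries, and its ratio was 142 (95% counting interval 48.4 to 692). Among the largest falls were TNFAIP8L2, a brake on immune receptor signalling (-6.72 ± 0.35), the ubiquitin ligase gene TRIM17 (-6.69 ± 0.36), TMEM136 (-6.55 ± 0.36) and the matrix gene CTHRC1 (-6.30 ± 0.28). Of 16456 genes tested, 2299 rose and 2674 fell, and 512 of the rises and 910 of the falls were at least 2-fold. Without parental replicate 2 the 4973 called genes became 3245.

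Replication-dependent histones were the only list called in PRO-seq. Of 16 tested, 15 rose and 0 fell, with a median of 1.32 (camera adjusted p = 7.22e-19, and adjusted p = 0.694 with an estimated correlation). HIST1H4H rose by 1.43 ± 0.13 and HIST1H1E by 1.65 ± 0.15, although reads of histone genes can be shared between paralogs. Apoptosis regulators had 7 rises, among them BCL2L11 (1.62 ± 0.12) and BCL2 (1.05 ± 0.13), 1 fall, BMF (-1.24 ± 0.28), and 15 not called (0.297). In the ALK STAT3 program 3 genes rose, such as ALK itself (0.76 ± 0.13), 8 fell, such as CD274, which encodes PD-L1 (-1.30 ± 0.15), and 11 fell when adjusted over the list alone. Drug efflux genes had 3 rises of 7, led by ABCC5 (0.69 ± 0.13), without a list call (0.341). Except for histones, members of the PRO-seq lists were not sorted by the chromosome stretches given below. Their changes may thus be shared with neighbouring genes. IMiD neosubstrates had 1 rise, PATZ1 (0.45 ± 0.10), and 3 falls, such as ZNF276 (-0.76 ± 0.14), of 15 tested (0.752, median above and mean below 0). Markers of B cells showed 0 calls among 3 tested (edgeR, 0.631), CD79A with an adjusted p of 0.125, and epithelial or stromal markers 1 fall of 2 (0.341).

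Cytokines were split in PRO-seq, with 3 rises, such as CCL20 (1.92), and 4 falls, such as IFNG (-3.68) and CSF1 (-3.26), of 10 tested (0.479). NF-kB targets had 4 rises, such as IER3 (1.74) and TRAF1 (1.58), and 2 falls of 18 (0.341). AP-1 and BATF factors had 2 rises, such as BATF (0.88 ± 0.10), and 4 falls, such as FOSB (-0.90 ± 0.16), of 15 (0.844). The CRL4 cereblon machinery had 4 rises, such as UBA3 (0.41 ± 0.09), and 3 falls, such as NEDD8 (-0.44 ± 0.08), of 24 (0.572). Cell cycle genes had 10 rises, among them BIRC5 (0.56 ± 0.11), and 1 fall of 30 (0.162). Interferon response genes went both ways, with OAS3 at -3.18 ± 0.31 and HERC6 at 2.39 ± 0.30, and 8 rises and 4 falls of 40 (0.341).

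RNA-seq asked the same question of steady RNA in the cells without doxycycline. CSNK2B rose by 0.86 ± 0.16 and CSNK2A1 fell by 0.99 ± 0.08, while CSNK2A2, the other catalytic subunit, rose by 1.44 ± 0.12. IKZF1 rose by 0.80 ± 0.10 (adjusted p = 1.53e-05), from between 514 and 641 to between 938 and 1050 CPM. IRF4 fell by 1.30 ± 0.10, and JUN, an AP-1 factor, fell as well. ZFP91 gave -0.22 ± 0.09 (adjusted p = 0.0536), and its adjusted p was 0.00852 with library size only, 0.0419 with DESeq2's size factors, 0.0352 with DESeq2 and 0.0309 with the filter at 1 CPM. CRBN gave 0.25 ± 0.11 (adjusted p = 0.0809).

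Several genes in RNA-seq went from next to nothing to clear levels or back. ITGA1, a collagen-binding integrin, was at least 187-fold higher in regrown cells. PIK3CG rose by 9.28 ± 0.49 and NETO2, which encodes a receptor accessory protein, by 9.22 ± 0.25. TP73, a p53 relative, had a ratio of 615 (95% counting interval 170 to 5080). SULF1, a heparan sulfate sulfatase gene, was at least 288-fold lower, ZNF74 at least 248-fold lower and PKN3, a kinase gene, at least 129-fold lower. Of 13379 genes tested, 3023 rose and 2827 fell, which became 2415 and 3546 with library size only, where the median of all genes shifted by -0.101, and 2799 and 3129 with no filter. With the library score given with the knockout as a covariate 2870 were called. The libraries of this table also differ along an axis of short against long genes, given with the knockout below, whose correlation with these changes across genes was -0.361. On it the parental libraries scored -4.7, 2.2 and 13.2 and the regrown ones -16.6, -7.7 and -24.4, so the groups did not overlap. The genes and lists of this comparison carry that limit, and they were not tested one by one with the covariate.

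Hypoxia and glycolysis genes were lower in regrown RNA, with 1 rise and 12 falls of 24 and 13 falls adjusted over the list alone (camera adjusted p = 0.000152, and adjusted p = 0.518 with an estimated correlation). Its largest named falls were CA9, a carbonic anhydrase (-3.84 ± 0.18), and BNIP3, a mitophagy gene (-2.57 ± 0.12). Myeloid markers had 4 falls, led by the scavenger receptor CD163 (-5.70 ± 0.15), and 1 rise, S100A9 (3.69 ± 0.22), of 7 (0.00389, and adjusted p = 0.518 with an estimated correlation). T cell receptor and identity genes had 6 rises, such as TRBC2 (3.63 ± 0.29), and 1 fall, CD5 (-0.85 ± 0.13), of 11. That list's adjusted p was 0.0125, then 0.518 with an estimated correlation, 0.0652 without parental WT replicate 2 and 0.0545 without regrown WT replicate 1. Mitochondrially encoded genes had 8 rises, such as MT-ATP8 (0.97 ± 0.09), and 1 fall of 13, or 9 rises adjusted over the list alone (0.0209). For them the adjusted p = 0.851 with an estimated correlation, and it was 0.0652 without parental WT replicate 2 and 0.0942 without regrown WT replicate 2.

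In DGE under DMSO the interferon-induced IFITM3 fell from 839 to 8.76 CPM in regrown cells (-6.56 ± 0.30, adjusted p = 1.94e-15), with reads that can be shared with IFITM1. PTPRC had 1 count over the parental libraries and a ratio of 194 (95% counting interval 34.4 to 7700). CSNK2B rose by 1.70 ± 0.16, CSNK2A2 by 1.11 ± 0.23, and CSNK2A1 fell by 1.13 ± 0.23. IRF4 fell, and IKZF1 was not called (0.47 ± 0.18, adjusted p = 0.136). CHI3L1, a secreted glycoprotein gene, rose by 4.02 ± 0.44, and TNS4, a focal adhesion gene, by 3.27 ± 0.51. HMGN5, which encodes a nucleosome binder, had 1 count in regrown libraries and a ratio of 45.0 (95% counting interval 7.69 to 1820), and CD163 fell by 3.88 ± 0.41. Of 5941 genes tested, 173 rose and 196 fell. The 369 called became 226 without parental DMSO replicate 1, 222 without parental DMSO replicate 2, 240 with DESeq2 and 209 without the genes in chromosome stretches.

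DGE named 6 lists, and with an estimated correlation none was called. MHC class I presentation had 5 rises of 13, such as HLA-E (1.59 ± 0.19) and HLA-C (1.74 ± 0.21), whose reads can be shared between HLA genes, and 1 fall adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.352 with an estimated correlation). Of the 5, 4 were HLA genes inside a raised stretch of chromosome 6 (53 genes in DGE, median 1.39), and of the 9 members outside it 1 rose. Hypoxia and glycolysis genes were lower as a list (0.011, adjusted p = 0.352 with an estimated correlation), with 1 fall of 18, CA9 (-2.39 ± 0.27). T cell genes were higher (0.0181, adjusted p = 0.352 with an estimated correlation), with 2 rises of 7 and 3 adjusted over the list alone. Casein kinase 2, with CSNK2B, CSNK2A2 and CSNK2A1 called (0.011, adjusted p = 0.352 with an estimated correlation), was at 0.068 without parental DMSO replicate 1. CSNK2B and CSNK2A1 moved with their neighbours in DGE (medians 1.52 and -0.91), and the neighbours of CSNK2A2 were not examined. The call of this list is therefore not set apart from changes shared along chromosome segments. The ALK STAT3 program had 1 rise and 3 falls of 18, such as EMP1 (-2.03 ± 0.37), or 2 and 4 adjusted over the list alone (0.0447, adjusted p = 0.436 with an estimated correlation), and stood at 0.0587 without parental DMSO replicate 2 and 0.339 without regrown DMSO replicate 2. Myeloid markers had 2 falls of 3, and 3 adjusted over the list alone (2.35e-05, adjusted p = 0.173 with an estimated correlation) and stood at 0.119 without regrown DMSO replicate 3.

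**Figure D1:**
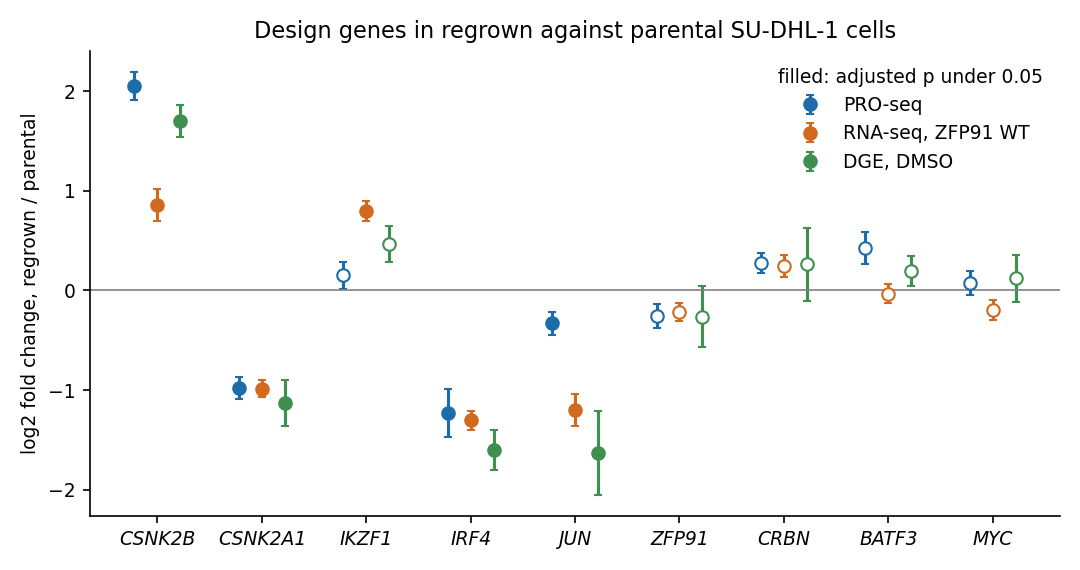
Log2 change of regrown over parental SU-DHL-1 cells (y axis) for 9 design genes in PRO-seq, RNA-seq and DGE, as fitted value ± SE from 3 libraries per group, filled where the adjusted p was under 0.05. CSNK2B was higher and CSNK2A1 and IRF4 were lower in all 3 assays.

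Calls in the 3 assays overlapped. PRO-seq and RNA-seq, among 11928 genes tested in both, shared 985 rises (439 expected, Fisher's exact p = 2.19e-201) and 1041 falls (406 expected, p = 3.59e-280), against 168 genes called in opposite directions. For PRO-seq and DGE the shared rises were 130 (25.2 expected) and the shared falls 145 (23.7 expected), and for RNA-seq and DGE 145 (45.7 expected) and 166 (46.0 expected). With an absolute log2 change of at least 1 in both, the shared calls of these 3 pairs were 527, 108 and 140. Correlations of log2 change across genes were 0.662, 0.675 and 0.641. In all 3 assays 116 genes rose and 131 fell, of 5558 tested, with PTPRC and CSNK2B among the first and CSNK2A1, IRF4 and CD163 among the second.

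Part of the called genes lay side by side. Running medians over 25 genes went beyond all 100 shuffles in 17 chromosome stretches of PRO-seq, with a largest median of 1.76 against 0.54 in the shuffles. One of them lay on chromosome 6 between 21.4 and 32.2 Mb, where the median change was 1.19 in PRO-seq, 0.99 in RNA-seq and 1.33 in DGE. CSNK2B lies there, and the 24 genes nearest to it had medians of 1.70, 1.23 and 1.52 in the 3 assays. The neighbours of CSNK2A1, on chromosome 20, stood at -0.88, -1.07 and -0.91. PTPRC rose apart from its neighbours (0.15, 0.16 and 0.19), and IRF4 fell beyond its own (-0.30, -0.37 and -0.49). Of all calls, 14.1% in PRO-seq, 9.81% in RNA-seq and 32% in DGE lay inside the stretches of their own assay. All 14 genes of the histone list tested in the raised chromosome 6 stretch rose in PRO-seq (median 1.35). So did 108 of the 125 genes there without a histone name (median 1.13). The CSNK2B level also differed by assay, with 17.1 CPM in parental RNA-seq and 415 CPM in DGE, and how reads from its overlapping neighbours were counted was not stated.

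**Figure D2:**
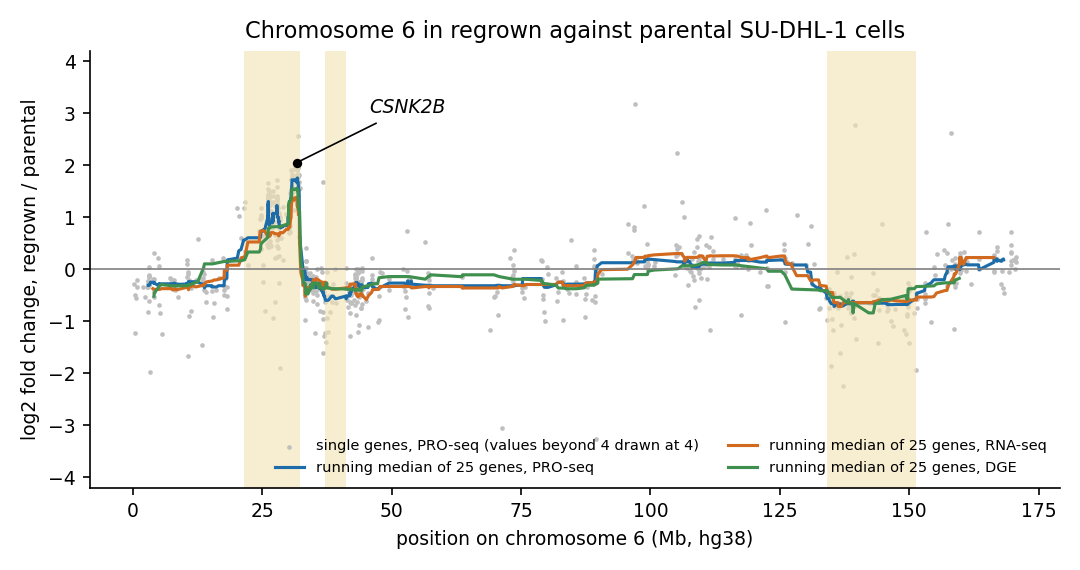
PRO-seq log2 change of regrown over parental cells (y axis) for genes along chromosome 6 (x axis, Mb), with running medians of 25 genes for PRO-seq, RNA-seq and DGE and the PRO-seq stretches shaded. CSNK2B is marked inside the raised stretch between 21.4 and 32.2 Mb.

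Which genes does lenalidomide move within 18 h? In parental cells IL10, which encodes an anti-inflammatory cytokine, fell by 3.10 ± 0.31, from 320 to 26.1 CPM, and NFKBIA, the NF-kB inhibitor gene, fell by 1.19 ± 0.23. LBP, which encodes a lipopolysaccharide-binding protein, had no counts under DMSO and was at least 59.1-fold higher under the drug. SPP1, which encodes the secreted protein osteopontin, rose from 8.22 to 333 CPM (5.33 ± 0.39, adjusted p = 2.04e-11), and SLC2A5, a fructose transporter, from 11.4 to 221 CPM (4.21 ± 0.36). FGG, a fibrinogen chain, rose by 3.96 ± 0.70 but had no adjusted p in DESeq2. The transglutaminase TGM2 rose by 3.63 ± 0.42, FCRLB, an Fc receptor-like gene, by 3.57 ± 0.32 and the scaffold gene AKAP12 by 3.55 ± 0.31. GTPBP8 fell by 1.89 ± 0.28. None of the design genes was called, with ZFP91 at -0.50 ± 0.31 (adjusted p = 0.69) and IKZF1 at 0.19 ± 0.25 (0.92). Of 5796 genes 39 rose and 10 fell. The 49 called became 29 without DMSO replicate 1, 25 without DMSO replicate 2, 30 without lenalidomide replicate 1 and 105 without lenalidomide replicate 3, the smallest library. They became 30 with DESeq2, 31 with the filter at 1 CPM, 28 with all 4 groups in 1 fit and 0 in edgeR after thinning every library to the smallest.

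Camera called 6 lists in parental cells under lenalidomide, and none with an estimated correlation. Cell cycle genes were lower (adjusted p = 0.000161, adjusted p = 0.125 with an estimated correlation) with 0 of 27 called by edgeR, where KIF11 gave -1.05 ± 0.32 (0.161), and 2 lower when adjusted over the list alone. Cytokines were lower (0.000373, adjusted p = 0.125 with an estimated correlation), with IL10 as 1 fall of 4. The ALK STAT3 program, which also holds IL10, had 2 falls of 19 and 4 adjusted over the list alone (0.00331, adjusted p = 0.201 with an estimated correlation). Interferon genes were higher (0.00221, adjusted p = 0.125 with an estimated correlation), with IFITM3 as 1 rise of 19 (1.58 ± 0.16) and 4 adjusted over the list alone. Myeloid markers had 2 rises of 3, such as CD163 (1.39 ± 0.24), and 1 fall adjusted over the list alone (0.00612, adjusted p = 0.176 with an estimated correlation). Mitochondrially encoded genes were higher, with 0 of 13 called and MT-CO2 at 0.38 ± 0.12 (adjusted p = 0.219). That list's adjusted p was 0.0202, then 0.641 with an estimated correlation, and without DMSO replicate 3, lenalidomide replicate 1 and lenalidomide replicate 2 it was 0.25, 0.0788 and 0.205.

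In regrown cells, which per the labels are resistant to the drug, SPP1 still rose under lenalidomide, by 4.93 ± 0.54 from 8.07 to 254 CPM. LBP had 2 counts under DMSO and a ratio of 30.9 (95% counting interval 7.97 to 265), and its adjusted p was 0.0608 without DMSO replicate 3. IFITM3 rose by 3.84 ± 0.57, the small GTPase gene RAB13 by 3.06 ± 0.49, PLAUR, the urokinase receptor gene, by 2.73 ± 0.35 and TM4SF1, a membrane protein gene, by 2.62 ± 0.23. IL10 was not called (-1.38 ± 0.47, adjusted p = 0.637, and 0.0356 with no filter). Of 5661 genes 283 had an unadjusted p under 0.05, no more than that threshold gives without any effect. In edgeR 13 rose and 0 fell. Without DMSO replicate 3 or lenalidomide replicate 3 the count was 7, and with no filter 20. Of the 13, 11 also rose in parental cells (0.0854 expected, Fisher's exact p = 1.26e-23), or 7 genes with DESeq2. Histones were lower as a list (0.000155, adjusted p = 0.219 with an estimated correlation), with 0 of 6 called and 4 lower when adjusted over the list alone. Messages of these histone genes lack a poly(A) tail, and how well DGE captured them was not tested, here or for the interaction below. Cell cycle genes were lower (0.0157, adjusted p = 0.678 with an estimated correlation), with 0 of 27 called and KIF11 at -0.88 ± 0.33 (0.8), and the list stood at 0.0608 without DMSO replicate 2 and 0.386 without lenalidomide replicate 1.

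Did the drug response itself differ between the backgrounds? The interaction called 0 of 6838 genes in edgeR, with a smallest adjusted p of 0.639, and 0 in DESeq2. An unadjusted p under 0.05 was seen for 285 genes in edgeR, no more than that threshold gives without any effect. With the replicate block, or without regrown lenalidomide replicate 3, 1 gene was called, IFITM3 (2.42 with adjusted p = 0.0306, and 2.73 with adjusted p = 0.0441, against adjusted p = 0.712 with all libraries and no block). ZFP91 stood at 0.45 ± 0.54 and IKZF1 at -0.20 ± 0.35. Simulated 2-fold differences were recovered in 8% of genes at this depth, so most differences of that size were not detectable here. Histones, with 1 of 6 lower when adjusted over the list alone, and the ALK STAT3 program, with 0 of 20 called, were the lists called (4.27e-05 and 0.0411, with adjusted p = 0.301 and adjusted p = 0.462 with an estimated correlation), and each lost its call without several libraries. Both were at 0.0511 without parental DMSO replicate 2. Histones stood at 0.159 without parental lenalidomide replicate 2, 0.0787 without regrown DMSO replicate 2, 0.0747 without regrown lenalidomide replicate 2 and 0.0795 without regrown lenalidomide replicate 3. The ALK STAT3 program stood at 0.157, 0.313, 0.227 and 0.235 without parental lenalidomide replicate 2, regrown DMSO replicate 2, regrown lenalidomide replicate 1 and regrown lenalidomide replicate 3, at 0.0527 without parental DMSO replicate 3, and at 0.0549 with the replicate block.

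**Figure D3:**
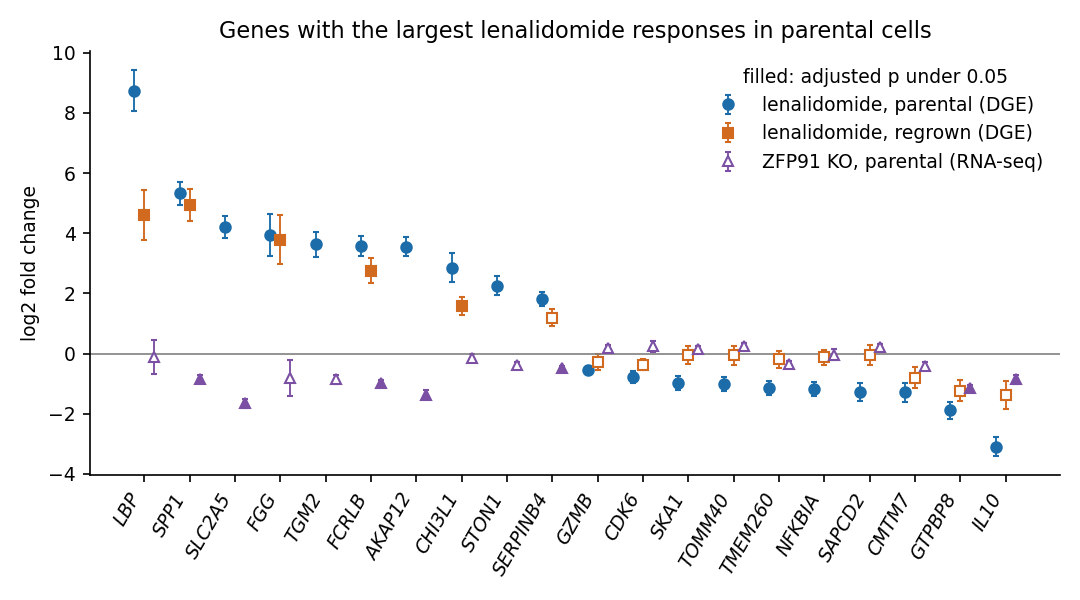
Log2 change (y axis, ± SE) of 20 named genes under lenalidomide in parental and regrown cells (DGE) and after ZFP91 knockout in parental cells (RNA-seq). The fitted value of LBP is no bound, and SLC2A5, AKAP12 and FCRLB were higher under the drug and lower after the knockout.

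What does knockout of ZFP91, a target of the drug, change? ZFP91 RNA itself measured 111, 116 and 110 CPM in parental cells without doxycycline and 93.4, 86.9 and 87.0 CPM after induction (-0.34 ± 0.08, adjusted p = 0.158, and 0.0246 with DESeq2). In regrown cells it measured 95.1, 95.2 and 88.1 against 98.6, 81.7 and 76.5 CPM (-0.12 ± 0.10, adjusted p = 0.395). Cas9 cuts leave small insertions or deletions that need not lower RNA, so these levels do not test the label. The knockout arm alone was given doxycycline, and no library here separates the knockout from doxycycline or from Cas9 cutting. In parental cells the cystine transporter SLC7A11 rose by 1.04 ± 0.17, VIM, which encodes vimentin, by 0.66 ± 0.08, and the serine synthesis genes PHGDH and PSAT1 by 0.87 ± 0.10 and 0.61 ± 0.08. Falls were led by the ephrin gene EFNA5 (-2.10 ± 0.27), SYTL3, a vesicle transport gene (-2.07 ± 0.20), and SLC2A5 (-1.66 ± 0.15). IRF4 gave -0.76 ± 0.13 (adjusted p = 0.0545), and its adjusted p was 2.63e-05 with DESeq2, 9.35e-11 with no filter, 0.0426 with library size only, 0.0285 with all 4 groups in 1 fit and 0.0386 with the replicate block. IKZF1 gave 0.04 ± 0.13.

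Of 13354 genes tested in parental cells 8 rose and 49 fell. The count rested on single libraries, with 0 genes without WT replicate 2, 11 without WT replicate 1, 16 without WT replicate 3, 110 without KO replicate 1 and 10 without KO replicate 3, so no call named here held without each library. With all 4 groups in 1 fit the adjusted p was 0.0687 for EFNA5, 0.154 for SLC7A11 and 0.0631 for PSAT1. DESeq2 called 198 genes and edgeR with no filter 231. A score of short against long genes, taken from an axis of regrown replicates and used as a covariate, gave 541 rises and 623 falls, and all 57 called genes were among them.

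Hypoxia and glycolysis genes were lower as a list in parental knockout cells, with 5 falls of 24 over all genes, 15 adjusted over the list alone and no rises (camera adjusted p = 7.66e-24, and 0.011 with an estimated correlation). Named members were PFKFB4, a regulator of glycolysis (-1.02 ± 0.11), ALDOC, an aldolase (-1.27 ± 0.17), and the glucose transporter SLC2A1 (-0.59 ± 0.08). The amino acid response and UPR list was higher, with 4 rises of 24 and 10 adjusted over the list alone (1.3e-14, and 0.0113 with an estimated correlation). These 2 calls held with every library left out. Cholesterol and fatty acid synthesis was lower with 1 fall of 25, INSIG1 (-0.69 ± 0.10), and 4 adjusted over the list alone (0.000119, adjusted p = 0.0606 with an estimated correlation). MYC and ribosome biogenesis was higher with 0 of 28 called, RRP9 standing at 0.32 ± 0.10 (0.000284, adjusted p = 0.0606 with an estimated correlation), and the ALK STAT3 program lower with 1 fall of 23, IL10 (-0.86 ± 0.14), whose own adjusted p was 0.0507 with the filter at 1 CPM, and 4 adjusted over the list alone (0.00744, adjusted p = 0.132 with an estimated correlation). NF-kB targets (0.00744) and drug efflux (0.00858) were lower with adjusted p = 0.132 with an estimated correlation. NF-kB targets stood at 0.0576 without KO replicate 1, and drug efflux, where MVP was the 1 fall of 7 (-1.01 ± 0.09), at 0.0888 without WT replicate 1 and 0.0727 without KO replicate 2. T cell genes (0.0227, adjusted p = 0.151 with an estimated correlation) stood at 0.107, 0.0576 and 0.0727 without WT replicate 1, KO replicate 1 and KO replicate 2. Cytokines (0.025, adjusted p = 0.227 with an estimated correlation) stood at 0.0925 without WT replicate 3, and mitochondrially encoded genes (0.000363, adjusted p = 0.508 with an estimated correlation) at 0.0695 without WT replicate 2.

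In regrown knockout cells hosts of small nucleolar RNAs, a group picked after the values were seen, were among the largest rises. SNHG8 rose by 1.77 ± 0.17, SNHG12 by 1.66 ± 0.20, SNHG1 by 1.64 ± 0.18 and GAS5 by 1.45 ± 0.12, and 16 of 20 such genes rose (median 1.27), against 0 of 20 in parental cells (edgeR, median -0.01). Of the 14 on the axis of short against long genes given below, 64.3% lay in its top 10%. CSNK2B rose by 0.95 ± 0.14, MYC by 0.49 ± 0.09 and BATF3 by 0.37 ± 0.08, while IKZF1 (-0.50 ± 0.08, adjusted p = 0.000689) and IRF4 (-0.49 ± 0.12) fell. Among the largest falls were SLC7A8, an amino acid transporter (-2.18 ± 0.45), NHSL1 (-1.97 ± 0.42) and TRANK1 (-1.51 ± 0.27). Of 13107 genes 2130 rose and 2056 fell, or 2047 and 2130 with DESeq2's size factors, and the 4186 called became 2410 without KO replicate 1 and 2464 without KO replicate 2. The libraries of this table also differed along an axis of short against long genes that was fixed on parental replicates alone, where it took 75.4% of the variance between replicates and correlated with gene length at -0.533 (Spearman, across genes). On it the regrown libraries scored -16.6, -7.7 and -24.4 without doxycycline and 14.4, 13.1 and 8.7 with it, so the arms did not overlap, and the axis correlated with the knockout's changes at 0.779 across genes. With that score as a covariate edgeR called 0 genes, 906 having an unadjusted p under 0.05, and the median absolute change of the 4186 went from 0.48 to 0.19 while its SE went from 0.11 to 0.24.

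**Figure D4:**
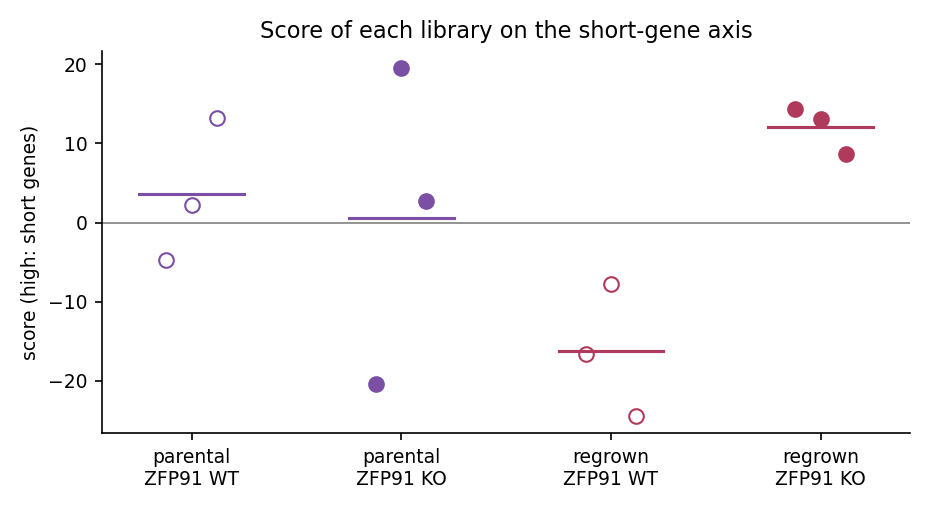
Score of each library of the ZFP91 knockout table on the axis of short against long genes (y axis), by group, with bars at the group means. The regrown groups do not overlap, and the parental groups do.

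Lists in regrown knockout cells share this limit. Mitochondrially encoded genes were lower with 7 falls of 13, such as MT-ND5 (-0.94 ± 0.11) and MT-ND6 (-0.95 ± 0.12) (0.000274, adjusted p = 0.707 with an estimated correlation), and stood at 0.0783 without WT replicate 2. The amino acid response and UPR list had 8 rises of 24, such as ATF4 (0.89 ± 0.12), and 11 rises and 1 fall adjusted over the list alone (0.0415, adjusted p = 0.707 with an estimated correlation). It stood at 0.076, 0.114 and 0.121 without WT replicate 1, WT replicate 2 and KO replicate 3. The CRL4 cereblon machinery was not called as a list (0.238) but had 7 rises, such as RBX1 (1.09 ± 0.19), NEDD8 (1.01 ± 0.18) and UBA3 (0.77 ± 0.09), and 4 falls, such as DDB1 (-0.44 ± 0.07), of 24. Cell cycle genes had 11 rises, such as UBE2C (1.15 ± 0.14), and 3 falls, such as MKI67 (-0.81 ± 0.10), of 30 (0.0968). IMiD neosubstrates had 2 rises, such as ZNF692 (1.05 ± 0.16), and 4 falls of 15 (0.452).

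Whether the knockout acted differently in the 2 backgrounds was tested as an interaction. It called 1399 of 14267 genes, 638 higher and 761 lower in regrown cells, or 977 and 463 with library size only and 1358 and 975 with no filter. It contains the contrast of the regrown arms, which stand apart on the axis of short against long genes, so its calls carry that library difference. IKZF1 was among them at -0.55 (adjusted p = 0.0405), but not with library size only (0.0564). It also lost the call without parental WT replicates 2 and 3 (0.091 and 0.123), parental KO replicates 1 and 3 (0.0797 and 0.0915), regrown WT replicates 1 and 3 (0.0914 and 0.103) or regrown KO replicates 1, 2 and 3 (0.11, 0.0948 and 0.0661). The count was 0 without parental WT replicate 2, parental WT replicate 3, parental KO replicate 3, regrown WT replicate 1, regrown WT replicate 3, regrown KO replicate 1 or regrown KO replicate 2. It was 587 without parental KO replicate 1, 3355 without parental KO replicate 2, 2686 without regrown WT replicate 2 and 542 without regrown KO replicate 3. DESeq2 gave 2441, no filter 2333 and the replicate block 2257. Mitochondrially encoded genes, with 6 of 13 lower and 8 adjusted over the list alone, were called with every library left out (2.2e-06, adjusted p = 0.827 with an estimated correlation).

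Do lenalidomide and knockout of its target ZFP91 move the same genes? In parental cells, among 5499 genes tested in both, 9 rose under the drug and fell after the knockout (0.25 expected), namely SLC2A5, AKAP12, FCRLB, SPP1, NLRP3, FBXO32, SERPINB1, SERPINB3 and SERPINB4, of which the last 2 are close paralogs. Both fell for IL10 and GTPBP8 (0.0618 expected, Fisher's exact p = 0.00162), and 0 rose in both (edgeR, 0.0355 expected, and 1 with DESeq2). With an absolute log2 change of at least 1 in both, 1 gene was shared in direction. These 11 genes were named after the overlap was seen. The correlation across all genes was -0.212. Every parental knockout call is lost without WT replicate 2, and no library separates the knockout from doxycycline or Cas9 cutting. In regrown cells 4 genes rose in both, ANXA1, CHI3L1, PLAUR and RGS16 (2.96 expected, p = 0.5), SPP1 and SYNPO went opposite ways, and the correlation was -0.0082. With that minimum the first count was 0 in edgeR. Between parental and regrown knockouts 13 falls were shared (7.07 expected, p = 0.022), such as AKAP12, STC1 and MVP, with PSAT1 as the 1 shared rise (1.35 expected) and a correlation across genes of -0.0179. These 14 shared calls became 47 with DESeq2 and 3 with an absolute log2 change of at least 1.

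What changed when CSNK2B was raised from a vector? In SU-DHL-1 its RNA went from between 29.4 and 30.7 to between 245 and 258 CPM (3.06 ± 0.05, adjusted p = 5.48e-25). NDNF, a secreted neurotrophic factor gene, had no counts with the empty vector and was at least 355-fold higher, at 19.3 CPM. SEPTIN11, a cytoskeletal GTPase, rose by 1.47 ± 0.11, the long noncoding RNA MIAT by 1.13 ± 0.17 and PHGDH by 0.82 ± 0.07. Falls were seen in TEX29 (-2.07 ± 0.12), SLC2A5 (-1.66 ± 0.06), PTPRC (-1.34 ± 0.23), IFNG, interferon gamma (-1.24 ± 0.23), and LCP2, a T cell adaptor (-1.16 ± 0.20). Smaller changes were seen in IKZF1 (0.19 ± 0.04, with its 24 neighbours at a median of 0.21), BATF3 (0.16 ± 0.04) and IRF4 (-0.19 ± 0.04), and none was called in ZFP91 (-0.04 ± 0.05), JUN (-0.06 ± 0.05) or CRBN (0.14 ± 0.06). Of 13727 genes 466 rose and 459 fell, or 453 and 468 with DESeq2's size factors, and 22 of the rises and 28 of the falls were at least 2-fold. The 925 called became 582 without empty vector replicate 1. Stretches beyond all shuffles were seen here too, on chromosome 7 between 1.57 and 56.1 Mb (153 genes, median 0.24) and on chromosome 17 between 30.8 and 41.7 Mb (78 genes, median 0.22), and 154 of the calls lay inside stretches. IKZF1 lies in the one on chromosome 7. DNA copy number was not measured here. A difference in these segments between vector and empty vector cells thus cannot be told apart from an effect of CSNK2B.

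Of the lists, 5 were called with CSNK2B in SU-DHL-1. MHC class II presentation had 5 falls of 8 and 6 adjusted over the list alone, such as HLA-DRA (-1.04 ± 0.10) and HLA-DPA1 (-1.18 ± 0.21) (2.09e-09, and 0.0338 with an estimated correlation), while MHC class I presentation, with 2 falls of 16, was not called (0.109). Hypoxia and glycolysis had 10 falls of 24 and 17 adjusted over the list alone, such as CA9 (-0.55 ± 0.04) and PFKP (-0.53 ± 0.04) (1.84e-12, adjusted p = 0.219 with an estimated correlation). Interferon genes had 7 falls of 43, such as IFITM3 (-0.55 ± 0.04), or 9 falls and 2 rises adjusted over the list alone (6.42e-05, adjusted p = 0.23 with an estimated correlation). p53 targets had 3 rises of 22, such as FDXR (0.25 ± 0.05), and 4 adjusted over the list alone (0.00346, adjusted p = 0.193 with an estimated correlation). Casein kinase 2 was called through CSNK2B, the 1 rise of 4 (1.56e-48, and 0.00698 with an estimated correlation).

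KI-JK, another ALK-positive line, answered with more genes. CSNK2B went from between 15.7 and 18.3 to between 76.7 and 81.3 CPM (2.19 ± 0.06, adjusted p = 2.56e-16). CD163 rose by 2.59 ± 0.09, SERPINB4, which has close paralogs, by 2.23 ± 0.24, PLA2G4A, a phospholipase, by 2.15 ± 0.10, IL1RN, the interleukin-1 receptor antagonist, by 1.67 ± 0.17 and SEPTIN11 by 1.16 ± 0.28. The long noncoding RNA BLACAT1 (-1.70 ± 0.19), ITGAX, which encodes integrin CD11c (-1.38 ± 0.07), and HILPDA, a lipid droplet gene (-1.33 ± 0.06), fell. JUN fell by 0.35 ± 0.04, CSNK2A1 rose by 0.23 ± 0.04 and MYC by 0.22 ± 0.04, and IKZF1 (-0.06 ± 0.04, adjusted p = 0.182) and IRF4 (-0.04 ± 0.03) were not called. Of 14104 genes 2591 rose and 2441 fell, or 2298 and 2736 with library size only, and 56 of the rises and 208 of the falls were at least 2-fold.

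In KI-JK 27 of 28 MYC and ribosome biogenesis genes rose and 0 fell, such as RRP12 (0.67 ± 0.04) and SRM (0.51 ± 0.04) (1.51e-27, and 0.0288 with an estimated correlation). Casein kinase 2, which holds CSNK2B itself, was the other list called under both settings (3 rises of 4, 1.76e-10 and 0.0295). Cholesterol and fatty acid synthesis had 15 falls and 2 rises of 23, or 16 falls adjusted over the list alone, such as INSIG1 (-0.72 ± 0.04) and MSMO1 (-0.79 ± 0.05) (6.33e-08, adjusted p = 0.0995 with an estimated correlation). MHC class II presentation had 9 falls of 13 and MHC class I presentation 11 falls and 1 rise of 17, such as B2M (-0.29 ± 0.03), with 10 and 12 falls adjusted over the list alone (0.000111 and 0.000232, adjusted p = 0.0995 and adjusted p = 0.125 with an estimated correlation). Interferon genes had 17 falls, such as GBP2 (-0.62 ± 0.05), and 5 rises of 41 (0.0038, adjusted p = 0.0995 with an estimated correlation). Hypoxia and glycolysis had 11 falls, such as PFKFB4 (-0.97 ± 0.06), and 1 rise of 24, with 14 falls adjusted over the list alone (0.000134, adjusted p = 0.127 with an estimated correlation). Heat shock and stress had 7 rises, such as HSPH1 (0.76 ± 0.04), and 3 falls of 16, or 4 adjusted over the list alone (0.00333), the amino acid response and UPR list 15 rises, such as HSPA5 (0.31 ± 0.03), and 1 fall of 25, or 2 adjusted over the list alone (0.0022), and myeloid markers 3 rises, led by CD163, and 1 fall of 6 (0.000604). For these 3 lists the adjusted p = 0.125 with an estimated correlation. The CRL4 cereblon machinery had 12 rises, such as GLUL (0.44 ± 0.05) and USP15 (0.34 ± 0.05), and 3 falls of 24, with 13 rises adjusted over the list alone (0.0207, adjusted p = 0.177 with an estimated correlation). Epithelial or stromal markers were not called as a list (0.139, but 0.00162 with the replicate block), with 3 falls of 4. These were KRT8 (-2.37 ± 0.64), KRT18 (-2.41 ± 0.66) and KRT19 (-2.12 ± 0.79), none of them called in DESeq2 (0.247, 0.308 and 0.497). Without empty vector replicate 3 they stood at 0.0781, 0.0831 and 0.232, and KRT19 stood at 0.11 without empty vector replicate 1 and at 0.129 and 0.147 without CSNK2B vector replicates 1 and 2.

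**Figure D5:**
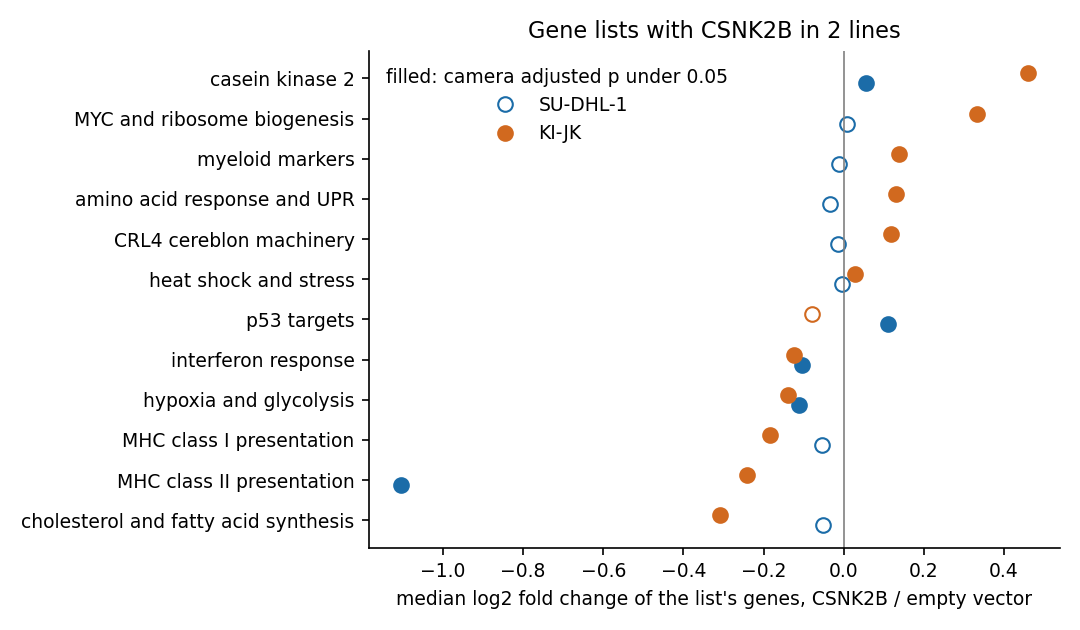
Median log2 change with the CSNK2B vector (x axis) of the members of 12 gene lists in SU-DHL-1 and KI-JK, filled where camera's adjusted p was under 0.05. MYC and ribosome biogenesis was raised in KI-JK alone, and hypoxia and glycolysis was lowered in both, with adjusted p = 0.219 in SU-DHL-1 and adjusted p = 0.127 in KI-JK with an estimated correlation.

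The lines shared 127 rises (87.3 expected, Fisher's exact p = 4.21e-06) and 189 falls (73.9 expected, p = 3.86e-40), with 115 genes called in opposite directions (161 expected) and a correlation across genes of 0.0841. With an absolute log2 change of at least 1 in both, 3 calls were shared. SEPTIN11 rose in both, and BIRC3, an apoptosis inhibitor gene, fell in both (-0.79 ± 0.06 and -0.47 ± 0.05). With the difference tested as an interaction, 1671 genes were higher and 1313 lower in KI-JK than in SU-DHL-1, or 1287 and 1611 with library size only and 911 and 1196 with no filter. MYC and ribosome biogenesis had 26 of 28 genes higher (4.12e-27, and 0.0104 with an estimated correlation). Thinned to the smallest SU-DHL-1 library, KI-JK still gave 4214 calls against 925, so depth alone does not account for its larger count.

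Did genes that differ in resistant cells respond to these perturbations? In SU-DHL-1 the vector raised CSNK2B RNA by 3.06 on the log2 scale. That is more than the rise in regrown cells, which was 0.86 in RNA-seq, 2.05 in PRO-seq and 1.70 in DGE. PRO-seq and DGE measure RNA differently from the RNA-seq of the vector cells. The value of 0.86 carries the library difference on the axis of short against long genes. Genes lower by at least 2-fold in regrown PRO-seq were lower after ZFP91 knockout in parental cells, with 15 falls and 0 rises of 484 (camera adjusted p = 7.65e-11), among them SLC2A5, STC1 and SULF1. They were also lower with CSNK2B in SU-DHL-1, with 76 falls, such as SLC2A5, and 8 rises of 552 (1e-07). They were higher under lenalidomide in parental cells, with 8 rises, such as SLC2A5, AKAP12 and CD163, and 0 falls of 97 (5.75e-11), but not when the set had no fold minimum (0.0598). Genes higher by at least 2-fold in regrown PRO-seq were higher with CSNK2B in SU-DHL-1, with 29 rises, such as PHGDH, and 9 falls of 283 (0.0013). These rises include CSNK2B itself, which the vector carried. Outside the stretches of PRO-seq and of this comparison, and so without CSNK2B, the set had 21 rises and 6 falls of 131 (0.00112). The full up set was not called in the other 2 parental comparisons. It had 2 rises and 0 falls of 282 after the knockout (0.0948), and 3 rises and 0 falls of 77 under lenalidomide (0.387). The 4 calls on the full sets held with an estimated correlation and with each library left out. In KI-JK with CSNK2B neither set was called. The up set had 38 rises and 75 falls of 312 (0.0927, and 0.731 with no fold minimum). The down set had 37 rises and 85 falls of 381 (0.0922, and 0.651 with no fold minimum). In regrown knockout cells they gave 0.573 and 0.0922, and the latter became 0.0317 without WT replicate 2 and 0.0219 without KO replicate 1. In both backgrounds the knockout results of these sets are not separated from doxycycline or Cas9 cutting.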

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

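All tests of the chromosome stretches, of the library score and of other splits of the samples reported in this part were chosen after the result was seen, while the 3 tests of a difference between groups were planned.

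The genes, lists and counts of the 3 interactions are given because the tests called a difference between 2 groups. For lenalidomide, regrown against parental, no gene passed, and 2 lists did, the ALK STAT3 program (camera adjusted p = 0.0411, higher, 0 of 20 genes called) and replication-dependent histones (4.27e-05, lower, 0 of 6 genes called). In edgeR 285 genes had an unadjusted p under 0.05, no more than that threshold gives without any effect, and DESeq2 called 0. Both lists lost the call with several libraries left out, as the report gives, with ranges of 0.0125 to 0.313 and 1.02e-05 to 0.159, and neither was called with an estimated correlation (0.462 and 0.301).

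For the ZFP91 knockout, regrown against parental, 1399 genes differed. IKZF1 stood at -0.55, and its call was lost with library size only (adjusted p = 0.0564). The largest positive differences were HLA-H 4.43, TREM1 2.24, PIK3R6 2.23, C19orf81 2.18, NECAB2 2.00, CCL20 1.93, S100A10 1.92, SNHG8 1.85, EFNA1 1.78 and TRPM4 1.77, where HLA-H is a pseudogene whose reads can come from other HLA genes. The largest negative ones were TIGD2 -3.86, MAP3K21 -3.27, SLC7A8 -3.01, STXBP6 -2.41, ZNF134 -2.37, NHSL1 -2.34, COL5A1 -2.20, MAPT -2.10, SCN3A -2.07 and HIST1H1E -2.07. DESeq2 gave no adjusted p for C19orf81, MAP3K21 and SLC7A8. The interaction contains the contrast of the regrown arms, which stand apart on the axis of short against long genes, so these calls and lists carry that library difference. Each of these calls was lost without at least 1 library, as the counts of 0 in the report imply. Cytokines, cell cycle genes and hypoxia genes were higher as lists (0.0222 each), and mitochondrially encoded genes lower (2.2e-06), none of them with an estimated correlation (0.367, 0.827, 0.827 and 0.827). Without parental WT replicate 1 the first 3 stood at 0.0507, 0.0557 and 0.0619, without parental KO replicate 2 at 0.086 each, without regrown WT replicate 3 at 0.0781 each, and without regrown KO replicate 1 at 0.0975, 0.0833 and 0.0975. Cytokines stood at 0.127 without regrown WT replicate 2, and cell cycle genes at 0.0692 without regrown WT replicate 1.

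For CSNK2B, KI-JK against SU-DHL-1, 2984 genes differed. Design genes among them were ZFP91 0.19, IKZF1 -0.24, CSNK2B -0.86, CSNK2A1 0.24, JUN -0.28, IRF4 0.16 and MYC 0.16. IRF4, MYC and ZFP91 were not called with library size only (adjusted p = 0.0537, 0.0646 and 0.113) or with no filter (0.322, 0.398 and 0.295), and SNX7 was not with no filter (0.0628). The largest positive differences were RND3 3.35, OR5BA1P 3.04, SNX7 2.99, PLA2G4A 2.77, CD163 2.61, IL1RL1 2.51, SERPINB4 2.44, RPSAP47 2.32, TEX29 2.25 and TM4SF1 2.15. The largest negative ones were NMB -5.01, DOCK6 -4.88, MNX1 -4.76, TCEAL8 -4.35, ZNF252P -4.34, SYT3 -4.22, CTSV -4.15, APOOL -4.07, B3GALT1 -3.56 and HAPLN3 -3.45. Fitted values of RND3, OR5BA1P, IL1RL1, RPSAP47, NMB, DOCK6, TCEAL8, ZNF252P, SYT3, CTSV, APOOL, B3GALT1 and HAPLN3, below 1 CPM in KI-JK, and of MNX1 and SNX7, below 1 CPM in SU-DHL-1, depend on the prior count and are no bounds.

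Several of these calls were lost with a library left out, at these adjusted p values. Of the KI-JK libraries, they were APOOL 0.0793, CTSV 0.0637, HAPLN3 0.0617, MYC 0.0527 and ZFP91 0.0771 without CSNK2B vector replicate 1. They were APOOL 0.0859, CTSV 0.0718, HAPLN3 0.0722, MYC 0.072, ZFP91 0.0967 and ZNF252P 0.0526 without CSNK2B vector replicate 2. They were APOOL 0.0957, CTSV 0.0796, IRF4 0.0859, MYC 0.0718, RPSAP47 0.159, SYT3 0.0545, TCEAL8 0.0542, ZFP91 0.0968 and ZNF252P 0.061 without CSNK2B vector replicate 3. They were APOOL 0.0924, IRF4 0.113, MYC 0.074, RPSAP47 0.0723 and ZFP91 0.191 without empty vector replicate 1. They were IRF4 0.0645, MYC 0.0951, RPSAP47 0.0582 and ZFP91 0.111 without empty vector replicate 2. They were APOOL 0.137, CTSV 0.189, DOCK6 0.0992, HAPLN3 0.162, NMB 0.0575, TCEAL8 0.119 and ZNF252P 0.104 without empty vector replicate 3. Of the SU-DHL-1 libraries, they were SNX7 0.0932 and ZFP91 0.123 without CSNK2B vector replicate 1. They were IRF4 0.111, MYC 0.112, SNX7 0.1 and ZFP91 0.134 without CSNK2B vector replicate 3. They were IRF4 0.0697, MNX1 0.0703, MYC 0.0586, SNX7 0.135 and ZFP91 0.194 without empty vector replicate 1. They were MYC 0.0814 without empty vector replicate 2. They were ZFP91 0.0643 without empty vector replicate 3.

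As lists, MYC and ribosome biogenesis (4.12e-27), MHC class II presentation (0.0119, 5 of 13 genes), the CRL4 cereblon machinery (0.00497, 10 of 24, and 1 lower adjusted over the list alone), heat shock and stress (0.007, 7 higher and 3 lower of 16, or 4 lower adjusted over the list alone) and myeloid markers (0.000483, 2 of 8) were higher in KI-JK than in SU-DHL-1. For myeloid markers the median (-0.69) and the mean were below 0 although the test gave a rise. Cholesterol and fatty acid synthesis (1.44e-06, 14 lower and 2 higher of 25, or 15 lower adjusted over the list alone) and p53 targets (0.00178, 6 lower of 22, or 9 adjusted over the list alone) were lower. With an estimated correlation MYC and ribosome biogenesis alone was called (0.0104).

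With 3 libraries against 3 there are 10 splits, so the share of splits with as many genes called cannot go below 0.1. In each of the 9 comparisons of 2 groups 1 of the 10 splits, the real one, gave as many genes. The real count and the highest other were 4973 and 0 for PRO-seq, 5850 and 0 for RNA-seq and 369 and 0 for DGE in regrown against parental cells. For lenalidomide they were 49 and 0 in parental and 13 and 1 in regrown cells, for the knockout 57 and 0 in parental and 4186 and 0 in regrown cells, and for CSNK2B 925 and 5 in SU-DHL-1 and 5032 and 0 in KI-JK. For the interactions 100 splits were drawn. For lenalidomide the real count was 0, so all 100 splits had to give as many (highest other 51), and this says nothing about chance. For the knockout 5 gave as many (real 1399, highest other 4330). For CSNK2B 2 of 100 gave as many (real 2984, highest other 3791), a share under 0.05. The splits with 51 and 3791 genes exchanged the arms of 1 background whole and so tested a sum of effects. For CSNK2B the splits that kept the KI-JK arms whole, exchanged or not, called 1909 or more genes, and the others at most 48. For the knockout the splits that mixed the regrown arms called at most 33, and those with as many genes as the real one kept the regrown arms whole, among them the one with 4330, which moved 1 parental library and points to a structure of the samples. Both shares thus follow the contrast within 1 background, and neither says whether chance can be excluded for the difference.

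Genes along stretches of chromosomes moved together between regrown and parental cells. A library effect of PRO-seq alone is argued against by RNA-seq, where 92.4% of 514 genes in the PRO-seq stretches had the sign of their stretch. Gains and losses of chromosome segments may explain the stretches, since the 24 genes nearest to CSNK2B had a median RNA-seq change of 1.23 and rose with it. Control of genes acting over whole segments would give the same picture (95.7% of 328 genes had the sign of their stretch in DGE), and the 2 cannot be told apart without DNA copy number, which was not measured in these tables. ChIP-seq input libraries of parental and regrown cells are in the series, but no values from them were available here. PTPRC and IRF4 changed beyond the median of their neighbours, so a segment that moves all of these genes alike is not enough for them. A gain or loss limited to either gene was not tested, and the neighbours of IRF4 were lower in median as well.

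Many more genes were called for the ZFP91 knockout in regrown than in parental cells. Library size is argued against by 4118 genes called in regrown cells after thinning to the smallest library. With 1 spread for all 4 groups 3672 were called in regrown and 54 in parental cells. That spread still holds the parental libraries, so it cannot decide whether they kept the parental count low. With a score from the axis of regrown replicates as a covariate the parental count went from 57 to 1164. The median SE of the 57 went from 0.11 to 0.08, so spread along that axis held the parental count down. A difference between libraries in the balance of short and long genes may account for much of it, since the axis from parental replicates correlated with the regrown changes at 0.779. With the library score as a covariate edgeR called 0 genes (906 at an unadjusted p under 0.05), because the median absolute change went from 0.48 to 0.19 and its SE from 0.11 to 0.24. As the score parts the regrown groups, a larger effect of the knockout there cannot be told apart from the library difference.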

How the results depend on the processing

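The covariate for the library score, thinning, leaving out genes in the stretches, and repeating lists and PRO-seq sets with each library left out or outside the stretches, and the shared calls of parental and regrown cells, were tests chosen after seeing the data, and the other tests were planned. No named gene, list or PRO-seq set that was called in the report was reversed under the alternatives run for it, which did not include the covariate for named genes and lists. With that covariate 2439 of the 4186 genes called in regrown knockout cells kept their sign. The larger direction of the calls changed in 7 comparisons, under 17 settings other than leaving out a library. With library size only there were 2415 rises and 3546 falls for regrown against parental RNA-seq, 977 and 463 for the knockout interaction, 2298 and 2736 for CSNK2B in KI-JK and 1287 and 1611 for the CSNK2B interaction. With no filter there were 2799 and 3129 for regrown against parental RNA-seq, 1358 and 975 for the knockout interaction, 437 and 487 for CSNK2B in SU-DHL-1 and 911 and 1196 for its interaction. With at least 1 CPM in 3 libraries there were 2859 and 2930 for regrown against parental RNA-seq and 751 and 735 for the knockout interaction. With DESeq2's size factors there were 2047 and 2130 for the knockout in regrown cells and 453 and 468 for CSNK2B in SU-DHL-1, and with DESeq2 2118 and 2245, 339 and 365, and 123 and 117 for regrown against parental DGE. That DGE comparison gave 136 and 129 with all 4 groups in 1 fit, and CSNK2B in SU-DHL-1 gave 560 and 611 with the replicate block. With a library left out the larger direction changed 11 times, in 4 comparisons. Counts within 1.5 times the reported one are not listed, and the cause was not tested for the changes below except where the alternative itself tests fewer genes or libraries.

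With DESeq2 the calls were 30 for lenalidomide in parental cells, 240 for regrown against parental DGE, 198 for the knockout in parental cells and 2441 for its interaction, with 7 shared lenalidomide calls and 47 shared knockout calls. With no filter they were 20 for lenalidomide in regrown cells, 231 for the knockout in parental cells and 2333 for its interaction. Lenalidomide in parental cells gave 31 with at least 1 CPM in 3 libraries, 28 with all 4 groups in 1 fit and 0 in edgeR after thinning to the smallest library. Without genes in the stretches regrown against parental DGE gave 209, from fewer genes tested. With the library score as a covariate RNA-seq gave 2870 for regrown against parental cells, 1164 for the knockout in parental cells (axis from regrown replicates) and 0 in regrown cells (edgeR, 906 at an unadjusted p under 0.05).

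The replicate block gave 2257 for the knockout interaction, 1 for the lenalidomide interaction, 8 lists for CSNK2B in SU-DHL-1 and 1 for the lenalidomide interaction, and it moved no other such count past 1.5 times. With an absolute log2 change of at least 1, shared calls were 527 for PRO-seq and RNA-seq, 108 for PRO-seq and DGE, 140 for RNA-seq and DGE, 3 for CSNK2B, 3 for the knockout, and 1 in parental and 0 in regrown cells for lenalidomide with the knockout, which follows from fewer genes passing. With no fold minimum the PRO-seq down set under lenalidomide stood at 0.0598.

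With an estimated correlation the lists called were 2 for the knockout in parental cells, 2 for CSNK2B in SU-DHL-1, 2 in KI-JK and 1 for its interaction, and 0 in the other 8 comparisons. With limma's rotation test they were 11 for PRO-seq, 8 for regrown against parental RNA-seq, 3 for DGE, 8 for CSNK2B in SU-DHL-1, 1 for the knockout interaction, and 0 for lenalidomide in regrown cells, its interaction and the knockout in regrown cells.

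With each library left out in turn, calls ran from 3245 to 5322 for PRO-seq, 222 to 512 for DGE and 4606 to 6401 for RNA-seq in regrown against parental cells. They ran from 25 to 105 for lenalidomide in parental and 7 to 13 in regrown cells and from 0 to 1 for its interaction. For the knockout they ran from 0 to 110 in parental cells, 2410 to 5519 in regrown cells and 0 to 3355 for the interaction, and for CSNK2B from 582 to 902 in SU-DHL-1, 4246 to 4666 in KI-JK and 2303 to 2874 for the interaction. The libraries concerned are named in the report.

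Lists called then ran from 1 to 3 for PRO-seq (3 without regrown replicate 3), 2 to 5 for regrown against parental RNA-seq (2 without parental WT replicate 2), 1 to 2 for lenalidomide in regrown cells (1 without lenalidomide replicate 1), 0 to 3 for its interaction, 1 to 3 for the knockout in regrown cells (1 without WT replicate 1, WT replicate 2 or KO replicate 3), 1 to 4 for its interaction (1 without parental WT replicate 1, parental KO replicate 2, regrown WT replicate 3 or regrown KO replicate 1) and 6 to 8 for CSNK2B in SU-DHL-1 (8 without CSNK2B vector replicate 3). The PRO-seq down set in regrown knockout cells ran from 0.0219 to 0.13, and the other sets kept their side of the threshold. Overlaps were not repeated with a library left out.

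Of 336 other direction counts 81 moved by more than 1.5 times. Of 2964 list values 121 lost and 62 gained a call, and of 14367 values of named genes 1272 lost and 69 gained one.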
